A study of Mus musculus with 6 samples.

How the data were processed

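Ribosome-bound mRNA was measured by RNA sequencing in 6 libraries, 3 from the diencephalon and 3 from cortical grey matter of adult mice. Per the labels' protocols, astrocyte ribosomes were tagged with haemagglutinin on Rpl22 after tamoxifen, RNA was purified on columns, cDNA was amplified with the Ovation system, and barcoded libraries were sequenced on an Ion Proton instrument. Amplified cDNA carries no molecular identifiers as far as the labels state, so counting intervals and floors cover counting error only. Replicates were separate pools of 3 mice per the labels, and no label says whether libraries with the same number in the 2 regions came from the same mice.

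Per the submitters' processing notes, the authors used RSEM and the mouse build mm9; the versions, the aligner and the strand setting are not given in the sources used here. Each deposited file gives per gene the expected count, the TPM, the FPKM, the gene length and the effective length. The deposited expected counts are estimates by which RSEM shares reads between transcripts, so 3.64% to 3.99% of values in a library were not whole, and members of near-identical gene families are uncertain. The deposited TPM and FPKM values are scaled by effective length and by the library total; TPM served as an alternative, and FPKM was not used further. Genes were named by the symbols in the files. No annotation of the build named by the submitters was used here, so no coordinates are given. The reads of Rn45s, the ribosomal RNA precursor, made up 1.77% to 4.48% of counts and were kept.

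Expected counts were rounded to whole numbers, which moved library totals by less than 7 counts. Totals ran from 1733140 to 2334240. Of 23955 genes in the files, 10568 passed edgeR's filterByExpr with a minimum count of 10. Counts were scaled by TMM and fitted with edgeR's quasi-likelihood model (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with region as the only term, robust estimation and Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 13.6%. Standard errors of log2 differences were taken from the quasi-likelihood F statistic. CPM values are counts scaled by TMM library size, and SDs are over 3 libraries. Changes beyond 1.5-fold were tested with glmTreat. For a gene without a count in a region, the fold was bounded with 3 counts over that group; with 1 to 3 counts the ratio of summed counts was given with an exact 95% interval.

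Gene lists, tests and alternatives were fixed before the data were examined. The 37 lists cover astrocyte markers, regional patterning, stem cell, cell cycle, BMP and SMAD, other signalling, functional and state genes, markers of other cell types, and sex-linked genes. Lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 35 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance and compares them with no other genes, were alternatives. Of the 16 lists that passed, 4 also passed with an estimated correlation: subcortical neuron, diencephalic patterning, non-telencephalic astrocyte and cortical excitatory neuron markers. Summed CPM of cell type lists were compared by exact permutation. Named genes followed a rule: the 10 largest log2 differences in each direction among genes past the threshold with at least 10 CPM in the higher region and no overlap of libraries; up to 4 members of each list with the smallest adjusted p; and Slc1a3, Rpl22, Smad4, Gfap, Mki67 and the sex-linked genes. Members beyond the first 4 of a list, and the imprinted and actin-related genes of the closing section, were named after their values were seen.

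Alternatives were RLE size factors, no count filter, a minimum count of 30, DESeq2 1.42.0, limma with voom, a block for the replicate number, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean TPM of at least 1, and leaving out each library. After the data were seen, a term for the 2 libraries with under 50 CPM of Y-linked genes and an offset removing the trend on gene length were added; the trend was a natural spline with 5 degrees of freedom.

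The scripts were tested on simulated counts with known changes for the comparison of diencephalon with cortical grey matter, on 10326 genes. Of the changed genes, 25.4% were recovered at 1.5-fold, 55.2% at 2-fold and 98.5% at 4-fold, and 13 of 10130 unchanged genes were called. These 13 were 9.85% of the 132 genes called, above the 5% aimed at, in a single simulated data set. Simulated lists of 20 genes raised 1.5-fold were recovered in 50 of 50 runs, and 2 of 50 unchanged lists were called at an unadjusted p under 0.05. These simulations drew genes independently and so did not test the preset correlation. Far fewer simulated genes were called than the 3133 of 10568 in the real comparison. The recovered shares therefore hold for a stricter cut-off on the unadjusted p. Pairs of libraries of one region differed by more than sampling noise, with a chi-square per degree of freedom of at least 2.71, so none was a repeat deposit. Results of some single genes are not reported here.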

Results

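The series measured ribosome-bound mRNA of astrocytes from 2 regions of the adult mouse brain. In these mice, tamoxifen given at 9 weeks activates a Cre recombinase expressed from the locus of the glutamate transporter Slc1a3, which switches the ribosomal protein Rpl22 to a version with a haemagglutinin tag. Ribosomes carrying the tag are then purified with an antibody, and the mRNA bound to them is sequenced. Mice were 3 months old and of both sexes, and each library held the material of 3 mice. There were 3 libraries from the diencephalon, taken without the tissue surrounding the third ventricle, and 3 from cortical grey matter freed of meninges and white matter. Expected counts summed to 2078790, 1840340 and 1882260 in diencephalon replicates 1 to 3, and to 2334240, 1946880 and 1733140 in cortical grey matter replicates 1 to 3. The ribosomal RNA precursor Rn45s took 3.52% to 4.48% of counts in the diencephalic libraries and 1.77% to 2.23% in the cortical ones. Cortical grey matter replicate 3 stood apart from the other cortical libraries, with a chi-square per degree of freedom of 7.47 and 6.48 against 2.71 between those. A gene with no count in a library could still have reached 1.31 to 1.86 CPM there, the value of 3 counts. Libraries of unpurified RNA were not analysed here, so levels are compared between regions and not with the surrounding tissue.

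The comparison asked which translated mRNAs differ between astrocytes of the 2 regions; the title of the series names proliferation, neural stem cell potential and Smad4. Of 10568 genes tested, 1574 were higher and 1559 lower in diencephalon than in cortical grey matter (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). A change beyond 1.5-fold was shown for 484 higher and 572 lower genes. On the deposited TPM scale, where the median of all genes lay at a log2 difference of 0.22, 2118 of 14296 tested genes were higher and 958 lower, or 68.9% higher against 50.2%. The libraries of the regions did not overlap for 4500 genes, or 42.6%, where chance gives 10%. The split between higher and lower genes varied with gene length. Among the 1058 shortest genes, 24 were higher and 215 lower, with a median log2 difference of -0.35. Among the 1057 longest genes, 302 were higher and 164 lower, with a median of 0.15. With the length trend removed, 1370 genes were higher and 1595 lower. In that setting 85.5% of the original calls were kept.

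Among the 10 genes with the largest higher values, Foxb1, Sim1, Lhx1 and Lhx9 were on the diencephalic patterning list and Pmch and Lhx9 on the list of subcortical neuron markers. Slitrk6, a transmembrane protein, was at 341 ± 71.2 CPM in diencephalon and 2.59 ± 1.92 in cortical grey matter (SD, n = 3 each). The LIM homeobox gene Lhx9 was at 160 ± 15.3 against 6.38 ± 0.17 CPM. Chrnb4, a nicotinic receptor subunit, Foxb1, a transcription factor, and Pmch, the precursor of melanin-concentrating hormone, had no count in the cortical libraries. Against a floor of 3 counts over the group they were at least 48.6-fold, at least 23-fold and at least 22.4-fold higher in diencephalon. Sim1 had 1 cortical count, which gave a ratio of 110 (95% exact counting interval 19.3 to 4376). Its edgeR adjusted p was 0.000539, and 0.0940 without cortical grey matter replicate 3 (range over alternatives 1.54e-19 to 0.0940). Ratios for Cngb1, Onecut3 and Lhx1, with 2 or 3 cortical counts, were 46.7 (12.6 to 391), 35.0 (11.7 to 172) and 34.0 (11.3 to 168). Baiap3 completed the 10 genes, at 24.6 ± 11.7 against 0.678 ± 0.826 CPM.

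In the other direction, Neurod6, on the list of cortical excitatory neuron markers, was at 33.7 ± 7.33 CPM in cortical grey matter and at 1.03 ± 0.920 CPM in diencephalon. Chrdl1, a secreted BMP antagonist made by cortical astrocytes, was 29.1-fold lower in diencephalon (3.68 ± 1.40 against 109 ± 25.8 CPM, edgeR adjusted p = 1.99e-11). The spectrin gene Sptan1 fell from 4986 ± 1669 CPM in cortex to 243 ± 38.2 CPM. Kcnv1, a potassium channel subunit, and Fbxo34 had log2 differences of -4.46 ± 0.23 and -4.39 ± 0.55 (SE). Thbd, which encodes thrombomodulin, was 21.7-fold and Omd 23.3-fold lower. Fgfbp1 had 1 count and Fam180a 3 counts in the diencephalic libraries, with cortex to diencephalon ratios of 106 (18.6 to 4226) and 28.8 (9.53 to 143). In the same libraries 11 of 12 meningeal and fibroblast markers were lower in diencephalon, with a sum 5.73-fold lower, or 2.84-fold without Ptgds, and the vascular sum was 2.15-fold lower, or 1.44-fold without Vtn.

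**Figure D1:**
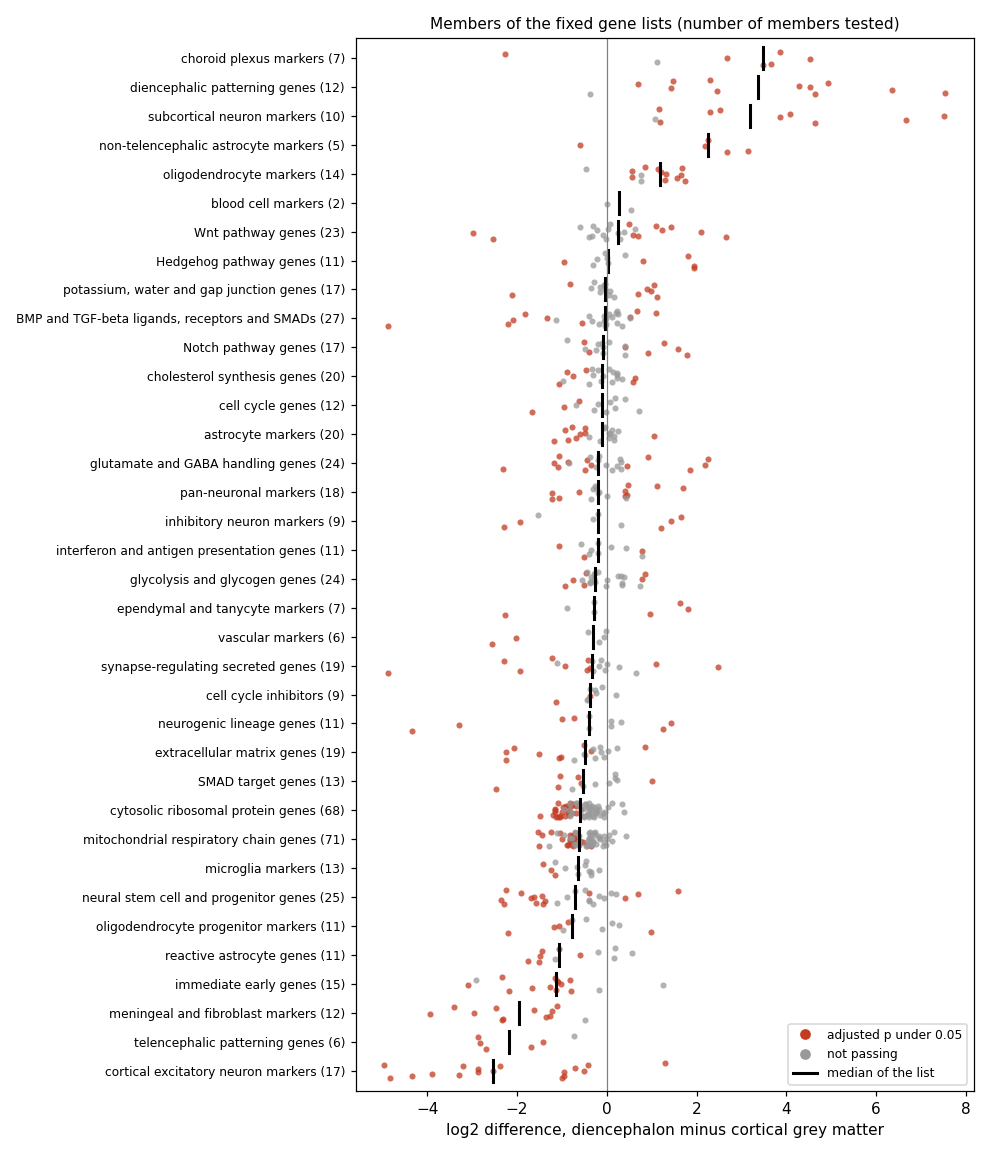
Log2 differences, diencephalon minus cortical grey matter, of the tested members of 36 gene lists, with a point per gene, red where its edgeR adjusted p was under 0.05 and grey otherwise. Each black bar is the median of a list, with genes without cortical counts at their fitted value, which is no bound, and medians ran from -2.54 for cortical excitatory neuron markers to 3.47 for choroid plexus markers.

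Genes of regional identity separated the libraries. Of 5 genes described as higher in astrocytes outside the telencephalon, 4 rose in diencephalon and 1 fell, also when adjusted over the list alone. Agt, which encodes angiotensinogen, was at 314 ± 19.3 against 34.5 ± 14.3 CPM, and the GABA transporter gene Slc6a11 at 2414 ± 350 against 503 ± 105 CPM. Itih3 was 6.37-fold and the glycine transporter gene Slc6a9 4.56-fold higher. The member that fell was Gfap, the astrocyte intermediate filament, at 212 ± 46.3 against 321 ± 33.4 CPM (edgeR adjusted p = 0.00367). On the TPM scale Gfap no longer passed (limma adjusted p = 0.107 and 0.112, range over alternatives 8.99e-05 to 0.112). Of 31 listed diencephalic patterning genes 12 passed the count filter, and 11 of these rose, 11 adjusted over the list alone. Tcf7l2 was at 279 ± 26.1 against 103 ± 9.23 CPM. Foxb1, Sim1, Lhx1 and Otx2, with 0 to 3 cortical counts, passed the filter through diencephalon alone and could only rise. The count of rising genes is therefore partly fixed by the filter. Lhx9 is also listed as a subcortical neuron marker and Otx2 as a choroid plexus marker. The non-telencephalic astrocyte and diencephalic patterning lists passed the set test with a preset and with an estimated correlation (camera adjusted p = 0.0300 and 0.0239 with an estimated correlation). Of 11 listed telencephalic patterning genes 6 passed the count filter, and 5 of these fell, or 6 adjusted over the list alone. Among them, Lhx2 was 7.06-fold, Emx2 7.33-fold and Nr2e1 3.25-fold lower in diencephalon, and Mfge8 also fell. The camera adjusted p of this list was 2.13e-09, and adjusted p = 0.157 with an estimated correlation.

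General astrocyte markers were lower in part. Of 20 tested, 8 fell, 1 rose and 11 did not pass, and 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.134). Glutamine synthetase, encoded by Glul, was at 2727 ± 221 CPM in diencephalon and 6121 ± 487 in cortical grey matter. Aldoc, a glycolytic enzyme, and Slc1a2, the main glutamate transporter gene, were 1.91-fold and 1.81-fold lower, while the bicarbonate transporter gene Slc4a4 was 2.08-fold higher. Slc1a3, whose locus drives the recombinase, was at 747 ± 32.1 against 1047 ± 270 CPM (log2 difference -0.49 ± 0.16 SE, edgeR adjusted p = 0.0244). That call was lost without any 1 of the 3 diencephalon replicates (edgeR adjusted p = 0.0803, 0.0817 and 0.0637), without cortical grey matter replicate 1 or 2 (0.0849 and 0.157), and on the TPM scale (limma adjusted p = 0.362 and 0.367). Over all alternatives its adjusted p ranged from 6.46e-06 to 0.367. Summed astrocyte markers were at 29705, 26450 and 25745 CPM in the diencephalic libraries, below each cortical one, and were 1.44-fold lower, or 1.25-fold without Slc1a2. Cortical grey matter replicate 3 was lowest among the cortical libraries, with 34649 CPM against 42583 and 40367. Without this library the list passed (camera adjusted p = 0.00223), as it did without a count filter (camera adjusted p = 0.0478, range over alternatives 0.00223 to 0.812). The tagged gene Rpl22 had a log2 difference of -0.24 ± 0.23 (adjusted p = 0.474).

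Neural stem cell and progenitor genes were more often lower than higher in diencephalon. Of 25 tested, 11 fell, 3 rose (Lfng, Sox1 and Notch1) and 11 did not pass, and 14 fell and 3 rose adjusted over the list alone. The heparin-binding growth factor gene Ptn was at 486 ± 78.5 against 2369 ± 578 CPM, and the transcription factor genes Nr2e1, Meis2 and Sox21 were 3.25-fold, 3.77-fold and 2.98-fold lower. The camera adjusted p was 0.000189, and adjusted p = 0.342 with an estimated correlation. Nr2e1 is also on the telencephalic patterning list and Vim on the reactive astrocyte list. In the same libraries the meningeal and fibroblast sum was 5.73-fold and the astrocyte marker sum 1.44-fold lower in diencephalon. The subcortical neuron, oligodendrocyte, choroid plexus and blood cell sums were higher. Which cells carried the changes in stem cell genes was not tested. Of 11 neurogenic lineage genes, 4 fell and 2 rose, the same numbers adjusted over the list alone. Tbr1, Neurod2 and Neurod1, transcription factors also listed as cortical excitatory neuron markers, were 20.4-fold, 9.76-fold and 2.01-fold lower. Of those markers 16 of 17 were lower in diencephalon, with a sum 3.76-fold lower, or 2.09-fold without Camk2a. Stmn1 also fell, and Cd24a and Dlx1 rose, the call for Cd24a being lost without diencephalon replicate 1 or cortical grey matter replicate 1 (edgeR adjusted p = 0.0658 and 0.0552, range over alternatives 0.00580 to 0.0658). The camera adjusted p of the list was 0.0378, and adjusted p = 0.261 with an estimated correlation. It also exceeded the threshold without diencephalon replicate 1 (0.0624) or cortical grey matter replicate 3 (0.0661), and ranged from 0.00629 to 0.261 over alternatives. Without a count filter, which raised its members from 11 to 18, the mean of the list turned from -0.63 to 0.07 and its call was lost (camera adjusted p = 0.106). The call was also lost with limma voom (0.207) and with the length trend removed (0.222), while the mean stayed at -0.63 in both. The median was -0.39 over the 11 members, 0.09 over the 18 without a filter, and 0.30 over 16 on the TPM scale, or 0.07 and 0.08 relative to all genes in the latter settings.

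Cell cycle genes were mostly too weakly expressed to test, with 12 of 48 listed genes past the count filter. Of these 3 fell (Ccnd2, Ccnd1 and Pcna), and 3 fell and 1 rose (Ccne2) adjusted over the list alone (camera adjusted p = 0.185). Cyclin D2, encoded by Ccnd2, was at 145 ± 22.8 against 461 ± 45.2 CPM, and cyclin D1, encoded by Ccnd1, at 39.3 ± 11.6 against 76.0 ± 7.57 CPM. The replication factor gene Pcna had an edgeR adjusted p of 0.0386, which became 0.121 and 0.182 without diencephalon replicate 2 or 3 and 0.0867 and 0.169 without cortical grey matter replicate 1 or 2. It also did not pass with DESeq2 (0.0697), on the TPM scale (0.165 and 0.172) or with the length trend removed (0.166), which moved its log2 difference from -0.61 to -0.40 (range over alternatives 0.00879 to 0.182). Ccne2, which encodes cyclin E2, was at 19.4 ± 3.12 against 11.7 ± 0.518 CPM (edgeR adjusted p = 0.0514). It passed as higher at a minimum count of 30 (0.0376), with a term for libraries with little Y-linked signal (0.0455) and on the TPM scale (limma adjusted p = 0.0292 and 0.0296, range over alternatives 0.0292 to 0.201). Mki67, a marker of proliferating cells, was at 9.50 ± 5.65 against 15.7 ± 2.64 CPM (log2 difference -0.69 ± 0.36, adjusted p = 0.159). Without diencephalon replicate 1 it passed, at -1.30 (edgeR adjusted p = 0.0167, range over alternatives 0.0167 to 0.490). Of 9 cell cycle inhibitors 2 fell, Btg2 and Rb1, also adjusted over the list alone (camera adjusted p = 0.285, and 0.0478 without a count filter, range over the camera alternatives 0.0478 to 0.428). Rb1 did not pass without diencephalon replicate 3 or cortical grey matter replicate 2 (edgeR adjusted p = 0.103 and 0.109) or on the TPM scale (limma adjusted p = 0.316 and 0.308, range over alternatives 0.00536 to 0.316).

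Smad4, the shared mediator of BMP and TGF-beta signals, was at 45.5 ± 7.79 CPM in diencephalon and 59.7 ± 3.73 in cortical grey matter, which did not pass (log2 difference -0.39 ± 0.18, adjusted p = 0.108). Among 27 ligands, receptors, SMAD proteins and antagonists, 6 fell, 3 rose (Acvr2b, Smad2 and Smad9) and 18 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0829, and 0.0317 without a count filter, range over the camera alternatives 0.0317 to 0.261). Ligand genes were among the lower ones: Bmp7 was at 20.6 ± 5.05 against 72.9 ± 16.7 CPM and Bmp4 at 4.98 ± 1.71 against 23.4 ± 3.95 CPM. Bmp4 is also listed as an oligodendrocyte progenitor marker, and the sum of those markers was 1.29-fold lower in diencephalon. Which cells carried the transcripts of these ligands was not tested. Ltbp1, which encodes a protein binding latent TGF-beta, was 4.26-fold lower. Of 13 SMAD target genes 5 fell and 1 rose, Smad7, with the same counts adjusted over the list alone (camera adjusted p = 0.103, and 0.0478 without a count filter, range over the camera alternatives 0.0478 to 0.261). Id4 was 2.12-fold, Pmepa1 1.57-fold and Ski 1.49-fold lower, and Id3 fell. Col1a1, 5.52-fold lower, is also a fibroblast gene, and the summed CPM of meningeal and fibroblast markers was 5.73-fold lower in diencephalon, or 2.84-fold without Ptgds.

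**Figure D2:**
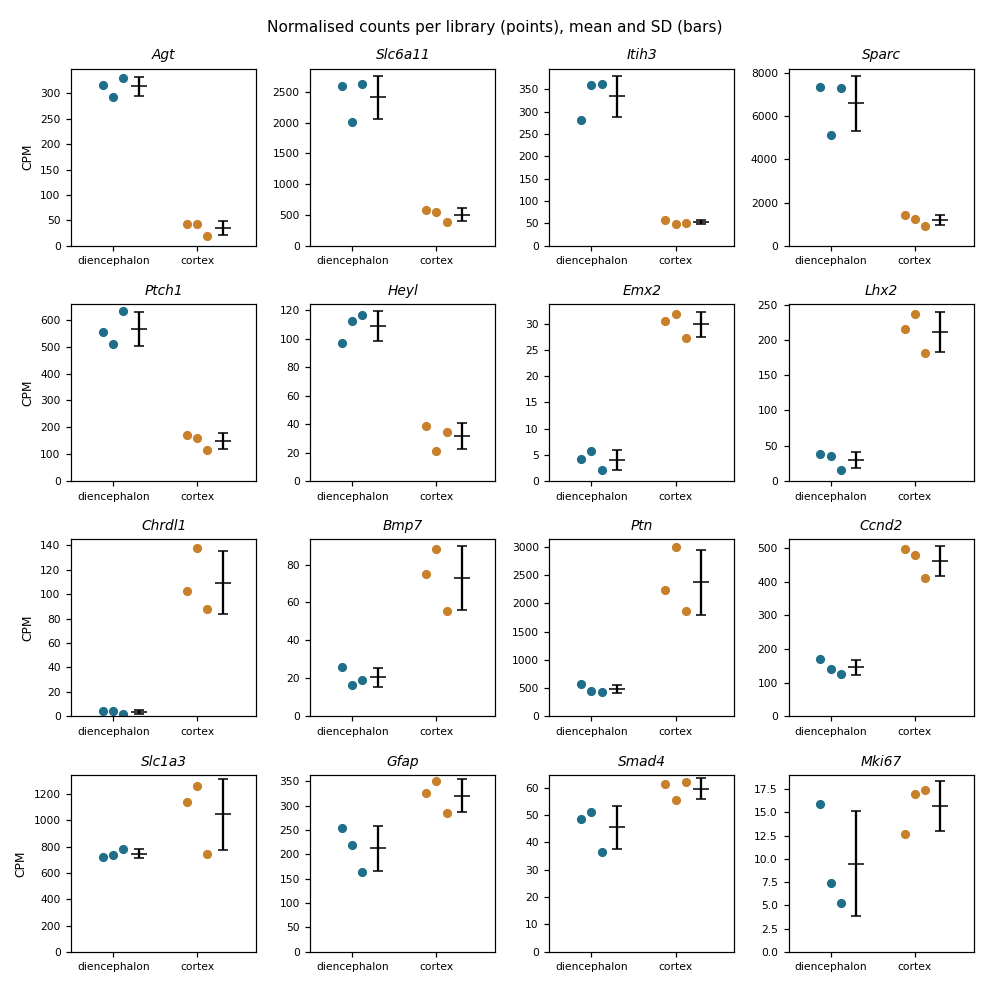
Normalised counts in CPM of 16 genes in the 3 libraries of each region, with a point per library and bars for the mean and SD; each vertical axis starts at 0. The libraries of the regions did not overlap for Agt, Slc6a11 and Ccnd2, while 1 diencephalic library of Mki67 lay within the cortical values.

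Other signalling lists held genes moving both ways. In the Hedgehog list 4 of 11 rose (Ptch1, Hhip, Gli1 and Sufu) and 1 fell (Gli3), and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0971, and 0.0317 without a count filter, range over the camera alternatives 0.0317 to 0.261). Ptch1, the receptor gene and a target of the pathway, was at 566 ± 62.4 against 148 ± 29.9 CPM, and the target gene Gli1 at 13.4 ± 4.29 against 3.32 ± 1.29 CPM. In the Notch list 5 of 17 rose (Heyl, Lfng, Notch3, Jag2 and Notch1) and 2 fell (Dner and Rbpj), or 6 and 3 adjusted over the list alone (camera adjusted p = 0.304). Heyl, Lfng and Notch3 were 3.43-fold, 3.00-fold and 2.40-fold higher, while Jag2 did not pass without diencephalon replicate 2 or cortical grey matter replicate 1 (edgeR adjusted p = 0.116 and 0.0771, range over alternatives 0.00702 to 0.116). The median of this list was -0.08 although its mean was 0.22 and the test pointed upward. In the Wnt list 8 of 23 rose and 2 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.598). The secreted modulators Dkk3 and Sfrp1 were 5.77-fold and 7.86-fold lower, and Sfrp5 was 6.29-fold higher, a call lost with log2(TPM + 0.1) (limma adjusted p = 0.0597, range over alternatives 4.98e-06 to 0.0597).

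Transport and metabolic lists were mixed as well. Of 24 glutamate and GABA handling genes 5 rose (Gria1, Slc6a9, Slc6a11, Abat and Gabbr2) and 8 fell, or 6 and 8 adjusted over the list alone (camera adjusted p = 0.791). The glutamate receptor gene Gria1 was 3.58-fold higher and the transporter gene Slc6a13, also listed among meningeal genes, 4.96-fold lower. Of 17 potassium, water and gap junction genes 5 rose (Kcnn3, Trpm3, Slc4a4, Kcnj10 and Slc12a2) and 2 fell (Gjb2 and Kcnk1), or 5 and 3 adjusted over the list alone (camera adjusted p = 0.347). The potassium channel gene Kcnn3 was 2.15-fold higher and the connexin gene Gjb2 4.33-fold lower. For both lists the median lay below 0, at -0.19 and -0.04, while the test pointed upward. Cholesterol synthesis genes had 2 of 20 higher (Srebf1 among them) and 4 lower (Fdft1, Msmo1, Nsdhl and Cyp51), the same adjusted over the list alone (camera adjusted p = 0.594), with Fdft1 2.10-fold lower and Srebf1 1.55-fold higher. Msmo1 did not pass on the TPM scale (limma adjusted p = 0.0714 and 0.0772, range over alternatives 6.39e-06 to 0.0772). Glycolysis and glycogen genes had 2 of 24 higher (Pfkfb3 and Slc16a1) and 4 lower (Aldoc, Ldha, Ldhb and Pfkp), the same adjusted over the list alone (camera adjusted p = 0.347), with Ldha 1.68-fold lower and Pfkfb3 1.79-fold higher. Ldhb did not pass without diencephalon replicate 3 (edgeR adjusted p = 0.0675), on the TPM scale (limma adjusted p = 0.165 in both) or with the length trend removed (edgeR adjusted p = 0.0703), which moved its log2 difference from -0.51 to -0.30 (range over alternatives 7.31e-05 to 0.165).

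Of 139 ribosomal protein and respiratory chain genes 54 were lower in diencephalon and none higher. Of 68 cytosolic ribosomal protein genes 27 fell and none rose, and 30 fell adjusted over the list alone, with Rpl31 at 94.2 ± 7.61 against 201 ± 32.8 CPM. Of 71 respiratory chain genes 27 fell and none rose, and 28 fell adjusted over the list alone, with Uqcr10 2.85-fold lower. The camera adjusted p was 9.87e-06 and 5.71e-05, and adjusted p = 0.261 for each list with an estimated correlation. Once the trend of expression on gene length was removed, the mean of the respiratory chain list moved from -0.56 to -0.22 and it did not pass (camera adjusted p = 0.0935, range over alternatives 4.61e-07 to 0.261), and that of the ribosomal list moved from -0.60 to -0.25 (camera adjusted p = 0.0441). These short genes have processed copies elsewhere in the genome, and reads shared with such copies make single members uncertain.

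In lists of secreted, matrix and reactive astrocyte genes, more members passed as lower than as higher in diencephalon. Of 19 synapse-regulating genes 8 fell and 2 rose (Sparc and Thbs1), or 9 and 3 adjusted over the list alone. Sparc, a matricellular protein, stood out at 6605 ± 1264 against 1178 ± 244 CPM, while the phagocytic receptor gene Mertk was 3.80-fold lower. Of 19 matrix genes 8 fell and 1 rose (Itga6), or 9 and 1 adjusted over the list alone. Hapln1, Cspg5 and Ncan, proteins of the perineuronal and parenchymal matrix, were 4.77-fold, 2.84-fold and 2.10-fold lower. Meningeal, fibroblast and vascular cells also make matrix, and the summed meningeal and fibroblast markers were 5.73-fold and the vascular markers 2.15-fold lower in diencephalon. Of 11 reactive astrocyte genes 6 fell and none rose, also adjusted over the list alone, with Serping1 2.86-fold and Vim 2.71-fold lower. Whether astrocytes or meningeal, fibroblast and vascular cells carried these changes was not tested. The camera adjusted p of the 3 lists was 0.0137, 0.000938 and 0.0179, and adjusted p = 0.502, 0.261 and 0.342 with an estimated correlation. The reactive list did not pass without cortical grey matter replicate 2 (0.0556) or at a minimum count of 30 (0.0768, range over alternatives 0.00547 to 0.342). Of 11 interferon and antigen presentation genes 1 rose (H2-K1) and 2 fell (B2m and Ifitm3), also adjusted over the list alone (camera adjusted p = 0.742). Each of these calls was lost without at least 1 library: H2-K1 without cortical grey matter replicate 1 (edgeR adjusted p = 0.0793, range over alternatives 0.00319 to 0.0793), B2m without cortical grey matter replicate 2 (0.0540, range over alternatives 0.00353 to 0.412), and Ifitm3 without diencephalon replicate 2 or cortical grey matter replicate 1 or 2 (0.0664, 0.0657 and 0.0813, range over alternatives 4.77e-05 to 0.177). B2m and Ifitm3 also did not pass on the TPM scale (limma adjusted p = 0.164 and 0.165 for B2m and 0.177 in both for Ifitm3) or with the length trend removed (edgeR adjusted p = 0.412 and 0.124), which moved their log2 differences from -0.50 to -0.17 and from -1.08 to -0.65. Immediate early genes, induced rapidly by activity or handling, had 12 of 15 lower and none higher, or 13 lower and 1 higher (Klf4) adjusted over the list alone. Egr1 was 4.51-fold and Egr3 8.58-fold lower (camera adjusted p = 3.99e-07, adjusted p = 0.157 with an estimated correlation). In the same libraries 16 of 17 cortical excitatory neuron markers were lower in diencephalon, and their sum was 3.76-fold lower, or 2.09-fold without Camk2a.

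Markers of other cell types were measured in the same libraries. Cortical excitatory neuron markers had 16 of 17 lower and 1 higher (Foxp2) in diencephalon, also adjusted over the list alone, with the vesicular glutamate transporter gene Slc17a7 at a log2 difference of -3.21 ± 0.20 (SE). Of 22 listed subcortical neuron markers 10 passed the count filter. Of these 9 were higher, or 10 adjusted over the list alone, with Slc17a6 at 237 ± 60.0 against 16.4 ± 1.42 CPM. Members without cortical counts, such as Pmch and Th, passed the filter through diencephalon alone and could only rise. The median log2 difference of the latter list was 3.18 as fitted and 3.07 with genes without cortical counts at their bound. Both lists passed with an estimated correlation (camera adjusted p = 0.0453 and 0.0239 with an estimated correlation). Pan-neuronal markers had 6 of 18 higher and 4 lower (Snap25, Syn1, Vsnl1 and Rbfox3), the same adjusted over the list alone (camera adjusted p = 0.598), with Snap25 2.34-fold lower and Snhg11 3.23-fold higher. Inhibitory neuron markers had 3 of 9 higher (Gad2, Slc32a1 and Dlx1) and 2 lower (Sst and Cck), the same adjusted over the list alone (camera adjusted p = 0.907), with Gad2 2.29-fold higher and Sst 3.83-fold lower.

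Oligodendrocyte markers had 11 of 14 higher and none lower, also adjusted over the list alone, and summed to 2337 ± 386 against 1077 ± 133 CPM. Mbp, which encodes a myelin protein, was 2.21-fold higher. Meningeal and fibroblast markers had 11 of 12 lower and none higher, also adjusted over the list alone, and summed to 1109 ± 222 against 6352 ± 1857 CPM, with Ogn 15.4-fold and Aebp1 5.03-fold lower. Choroid plexus markers had 5 of 7 higher (Prlr, Otx2, Clic6, Slc4a5 and Ttr) and 1 lower (Kcnj13), or 6 and 1 adjusted over the list alone, with Prlr 11.1-fold higher and a sum of 342 ± 55.2 against 61.6 ± 22.1 CPM. For these 3 lists the camera adjusted p was 4.03e-07, 7.3e-16 and 9.21e-05, and adjusted p = 0.261, 0.221 and 0.261 with an estimated correlation. The sums of a list cannot pass a two-sided exact permutation test of 3 against 3 libraries, whose smallest p is 0.1, the value reached for the 3 lists. The same permutation p was reached by the sums of each other cell type list except those of inhibitory neurons (exact permutation p = 0.5), microglia (exact permutation p = 0.2) and blood cells (exact permutation p = 0.4). Single genes carried much of some sums. Ependymal and tanycyte markers summed to 199 ± 54.9 against 579 ± 43.2 CPM, but without Dio2 to 94.4 ± 17.6 against 77.3 ± 24.0 CPM. Vascular markers summed to 121 ± 18.4 against 260 ± 61.5 CPM, and without Vtn to 88.5 ± 10.1 against 128 ± 7.02 CPM. Without Ptgds the meningeal and fibroblast sum was 2.84-fold lower, and without Prlr the choroid plexus sum was 150 ± 15.6 against 44.4 ± 21.4 CPM, or 3.38-fold higher in place of 5.56-fold.

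The remaining lists did not pass the set test. Oligodendrocyte progenitor markers had 4 of 11 lower (Bmp4, Gpr17, Pdgfra and Cspg4) and 1 higher (Lhfpl3), also adjusted over the list alone (camera adjusted p = 0.0971, and 0.0406 without a count filter, range over the camera alternatives 0.0406 to 0.261), with Gpr17 2.26-fold lower. Of 13 microglia markers 3 fell (Cx3cr1, P2ry12 and Fcrls), also adjusted over the list alone (camera adjusted p = 0.0637). Their sum ranged from 454 to 823 CPM in diencephalon and from 628 to 1465 CPM in cortex, the highest in cortical grey matter replicate 3. The list passed without a count filter (0.0266), with the replicate block (0.0442), with limma voom (0.0101), with the Y-linked term (0.00266), with the length trend removed (0.0292), without diencephalon replicate 2 (0.00209) and without cortical grey matter replicate 1 (0.000177; range over alternatives 0.000177 to 0.720), and Fcrls did not pass without diencephalon replicate 1 or 3 (edgeR adjusted p = 0.0548 and 0.0625), with the replicate block (0.0559) or on the TPM scale (limma adjusted p = 0.0880 and 0.0965, range over alternatives 6.15e-05 to 0.0965). P2ry12 did not pass with log2(TPM + 0.1) (limma adjusted p = 0.0537, range over alternatives 4.28e-09 to 0.0537). Of 6 vascular markers 2 fell (Cdh5 and Vtn), also adjusted over the list alone (camera adjusted p = 0.0831, 0.0377 without cortical grey matter replicate 3, 0.0386 with the replicate block, 0.0304 with the Y-linked term, and 0.0304 to 0.279 over the camera alternatives). Ependymal and tanycyte markers had 3 of 7 higher (Foxj1, Gpr50 and Scn7a) and 1 lower (Dio2), also adjusted over the list alone (camera adjusted p = 0.907). Their median was -0.29 and their mean 0.10 while the test pointed downward, and Scn7a did not pass without diencephalon replicate 1 or 3 or cortical grey matter replicate 1 (edgeR adjusted p = 0.0624, 0.0878 and 0.106), with DESeq2 (0.0603) or on the TPM scale (0.0828 and 0.0835, range over alternatives 0.0177 to 0.106). The median of the ependymal and tanycyte list was 0.98 on the TPM scale with 13 members and 1.15 in the counts without a filter with 15 members. Of the blood cell markers 2 were tested, too few for a set test, and Hbb-b1 and Hba-a1 had log2 differences of 0.54 and 0.01 (edgeR adjusted p = 0.360 and 0.998).

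Sex-linked genes showed that the pools differed in make-up. Ddx3y was at 63.2, 6.85 and 73.2 CPM in diencephalon replicates 1 to 3 and at 59.8, 57.0 and 0 CPM in cortical grey matter replicates 1 to 3. Xist was at 43.8 CPM in diencephalon replicate 2 and 137 CPM in cortical grey matter replicate 3, and between 0 and 4.21 CPM in the others. Usp9y had no count in any library.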

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

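The term for libraries with little Y-linked signal and the removal of the length trend were chosen after the data were seen. The count of genes differing between regions was 3133 and ranged from 2331 to 3373 when 1 library was left out, from 1145 to 1681 for higher and from 1186 to 1692 for lower genes. The count beyond 1.5-fold was 1056 and ranged from 850 to 1133. Counts under the other alternatives lay within 1.5 times, except for lower genes on the TPM scale, 958 with a pseudocount of 1 and 908 with 0.1; there the median of all genes was 0.22 and 0.23 against 0.01, and 14296 genes were tested instead of 10568, so scale and gene set both changed. Deviations from the regional means were hardly correlated between libraries with the same replicate number, at 0.06, -0.10 and 0.00. Such values cannot exclude shared mice. The replicate block gave 3037 genes. In diencephalon and cortical grey matter, Xist was at 43.8 and 2.13 CPM in replicate 2, and at 1.57 and 137 CPM in replicate 3. Uty was at 0 and 43.7 CPM in replicate 2, and at 47.6 and 0 CPM in replicate 3. These values argue against the same mice for those 2 numbers, while replicate 1 showed no such contrast.

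The number of lists past the threshold was 16, from 15 to 17 with 1 library left out, 22 without a count filter and 4 with an estimated correlation. There the stem cell list, with a mean of -0.80, was lost. Without a count filter the BMP and TGF-beta list (-0.53) and the SMAD targets (-0.52) passed, as they did by fry (-0.41 and -0.44), which asks another question. The Hedgehog, cell cycle inhibitor, oligodendrocyte progenitor, microglia and astrocyte marker lists also passed without a filter (camera adjusted p = 0.0317, 0.0478, 0.0406, 0.0266 and 0.0478). By fry 23 lists passed. Leaving out 1 library gave means from -0.89 to -0.68 for the stem cell list, -0.47 to -0.37 for the BMP and TGF-beta list and -0.57 to -0.23 for the SMAD targets. Cell cycle genes ranged from -0.40 to 0.041, changing sign without diencephalon replicate 3. The neurogenic list, which was called, changed sign and lost its call without a filter (0.073, camera adjusted p = 0.106). Sign changes without a call also occurred for glutamate and GABA genes (0.13 without a filter, -0.13 to 0.024 with a library left out), potassium genes (-0.040 to 0.13), pan-neuronal (-0.12 to 0.091) and ependymal markers (-0.075 to 0.23). The cause was not tested.

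Of 148 named genes run under alternatives, 124 kept their direction and side of the threshold in each. Genes named outside the rule were not rerun. Most named genes were chosen for large differences or small adjusted p, so this share does not hold for all genes. Of all 3133 called genes, 71.3% were also called without diencephalon replicate 3, the lowest share, and 99.9% with the Y-linked term, the highest. Sign changes occurred for 2 uncalled genes. Kdr was at 0.014 and 0.022 on the TPM scale with a pseudocount of 1 and 0.1. Hba-a1 was at -0.0038 with RLE, -0.18 with the replicate block, -0.016 with DESeq2, -0.33 with voom, -0.12 on both TPM scales, and from -0.64 to 0.51 with a library left out; the cause was not tested. Among simulated 1.5-fold changes 25.4% were recovered, and small changes may have been missed. That simulation called 132 of 10326 genes, against 3133 of 10568 in the real comparison. Fewer calls made its cut-off on the unadjusted p stricter, so 25.4% does not give the sensitivity of the real comparison.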

Other observations

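The tests on neuronal shares, on the neuronal origin of regional genes and on imprinted genes were chosen after the result was seen, as were the lists of imprinted, actin-related and microtubule genes.

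Several imprinted genes were among the most different genes. Zim1 was at 216 ± 43.3 CPM in diencephalon and 18.9 ± 5.17 in cortical grey matter (SD, n = 3 each), Dlk1 had a log2 difference of 3.42 ± 0.16 (SE), and Peg10 and Magel2 were 5.88-fold and 13.5-fold higher. Of 32 tested genes known to be imprinted in the mouse, 19 rose, 3 fell and 10 did not pass. The hypothesis that the set is higher in diencephalon was met, with a camera adjusted p of 2.88e-12 over 3 lists and an adjusted p of 0.0243 with an estimated correlation. The list was written after some of its members were seen to lead the table, so this is no independent evidence.

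Genes on the lists of region-specific neurons were among the most different genes of a purification aimed at astrocytes. Pan-neuronal markers lay at percentile 87.0 of expression among tested genes, which is consistent with RNA of local neurons in the purified material, either bound to tagged ribosomes or carried over. Pan-neuronal markers, 6 higher and 4 lower, had a median log2 difference of -0.19. It lay 2.35 or more from the medians of subcortical and cortical neuron markers, 3.18 and -2.54, beyond the pan-neuronal interquartile range of 0.76. Those 2 lists were chosen as regional, so their medians had to lie apart. The distance therefore cannot decide whether the share of neuronal RNA differed between the regions. The pan-neuronal sum was 4556 ± 198 CPM in diencephalon and 5610 ± 1012 in cortical grey matter, 1.23-fold lower, or 1.04-fold without Snap25. A different share stays open. Expression of the region-specific neuronal genes in astrocytes themselves was not tested and stays open as well.

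Ribosomal protein and respiratory chain genes had a median log2 difference of -0.60 over 139 genes. Thinned to the smallest library, the median was -0.58. Counts were scaled by library size, and thinning leaves the expected scaled ratios as they were. The thinning therefore cannot decide whether depth played a part. Totals overlapped, from 1733140 to 2334240 in cortex and from 1840340 to 2078790 in diencephalon. Leaving out any 1 library, the deepest cortical one included, kept the ribosomal mean between -0.66 and -0.52. The respiratory chain mean stayed between -0.64 and -0.52. For these 2 lists, the values argue against deeper cortical libraries as the cause. Gene length stays open. Removing the trend on length moved the median to -0.24 and the calls from 54 lower genes to 19 lower and 1 higher. A bootstrap over the 139 genes gave an interval of -0.31 to -0.17, which included the bound of -0.2 set beforehand. It resampled genes and not libraries, so it does not measure the spread between libraries. The use of the interval was decided after the value was seen. A length-dependent recovery of mRNA may therefore account for much of this difference, and a regional difference remains untested.

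Genes of actin-binding and actomyosin proteins were mostly lower in diencephalon, with 41 of 65 lower and 3 higher. Dbn1 was at 29.8 ± 3.78 against 405 ± 84.0 CPM (SD, n = 3 each), and Myh10 was 9.80-fold lower. Both were highest in cortical grey matter replicate 3, at 486 and 3752 CPM. The cortical excitatory neuron sum was also 3.76-fold lower in diencephalon, or 2.09-fold without Camk2a. The meningeal and fibroblast sum was 5.73-fold lower, or 2.84-fold without Ptgds. A larger share of neuronal RNA in cortex cannot be told apart from other causes, since the pan-neuronal median lay 0.51 above that of the actin families (-0.70), within the interquartile range of 0.76 of those markers. Co-purification through actin-binding proteins could not be separated either. The actin families lay at percentile 0 of 10000 expression-matched random lists, but the list was written after members were seen to be lower, so this is no independent evidence, and the microtubule and neurofilament families also lay at percentile 0.39. A regional difference in astrocytes stays open.

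The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3133 genes, and the highest other split 0; for changes beyond 1.5-fold the values were 1056 and 0, so 1 split of 10 reached the real value in each case. For gene lists the real split gave 16 and the highest other 19, and 4 of the 10 splits gave as many lists as the real one. The 3 other splits with at least as many lists each parted cortical grey matter replicate 3 from the other cortical libraries. The remaining splits still gave from 6 to 8 lists, with 0 genes called. With the preset correlation, lists were thus called in every split, also where no gene passed. Each other split mixed the regions unevenly, so part of the regional difference remained and none shows what chance alone gives. Whether the structure of the samples played a part was not tested.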
